A study of Mus musculus with 3 samples.

How the data were processed

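Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on the caudate putamen, the dorsal part of the striatum, of wild-type male mice of mixed genetic background. Per the labels, 3 libraries were made, 1 per antibody: against the retinoic acid receptor beta (RARβ), against histone H3 trimethylated at lysine 4 (H3K4me3), and against GFP. Peak lists of the RARβ and H3K4me3 libraries were used here. The anti-GFP library was not analysed here. Per the labels' protocols, libraries were amplified by PCR and read as single ends.

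Base calling with CASAVA 1.8.2, alignment with Bowtie and genome build mm9 are named in the submitters' processing notes. Peaks were called with MACS 1.4.2 on each library alone, without pooling, per the file headers. Both lists were called against the same control library, at a p cutoff of 1e-05, with a band width of 300 bp and an effective genome size of 1.87e+09 bp. The headers do not say which antibody made the control. At most 1 tag was kept per position, so the redundant tags of each library were removed before peak calling. For RARβ the larger control was scaled down to the smaller library. For H3K4me3 the control was scaled up to a library with 12.8 times as many filtered tags, so its local background rests on few control tags.

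Tag counts per peak were deposited as whole numbers without normalization. Fold enrichment, the ratio of the tag pileup at the summit to the local background, was given by the authors' peak caller. The deposited peak score is −10 times log10 of the peak's p-value. Its column name was lost in the deposited tables and was recognised from the MACS column order and from values that start at the cutoff of 50. A score of exactly 3100 was shared by 31.6% of the H3K4me3 peaks, and 208 had a higher one. An empirical FDR in percent was also deposited for every peak. Coordinates are given as in the files, counted from 1.

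Depth was taken from the file headers. The RARβ library held 4994799 tags, of which 2237580 were left after 55.0% were removed as redundant. The H3K4me3 library held 60367942 tags, of which 47461843 were left. The control had 3703580 filtered tags. Exact Poisson 95% intervals are given for tag counts and for numbers of peaks, and Wilson 95% intervals for shares. They cover counting error only, since tags from PCR-amplified libraries carry no molecular identifiers. There was 1 library per antibody, so no value has a replicate error, and each p-value describes positions within these libraries, not variation between animals. Peaks are not independent replicates.

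Peaks were counted as shared when they had at least 1 bp in common. The number shared was compared with 10000 circular shifts of the RARβ peaks, as a two-sided permutation test. Each shift used 1 random offset per chromosome over the span covered by either list. Shifted peaks could land where no read can be placed, and were not kept in regions rich in H3K4me3 peaks. The shifts can therefore give too few peaks in or near H3K4me3 peaks. Medians of groups of peaks were compared by 100000 two-sided permutations of the group labels, with 95% bootstrap intervals from 2000 resamples of peaks. Numbers per chromosome were compared with those of the H3K4me3 list by a chi-square statistic with 100000 multinomial draws. Families of tests were adjusted by the Benjamini-Hochberg method. Calculations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.

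The tests were checked on simulated lists of 8075 peaks. With peaks placed at random, the shift test called 1 of 40 simulations, and with 2% of the peaks planted on H3K4me3 summits it called 40 of 40. The median test called 4 of 100 simulations without a difference, 52 of 100 with fold values raised by a factor of 1.03, and 100 of 100 with a factor of 1.3. The chromosome test called 27 of 400 simulations without a difference and 400 of 400 with X lowered to 30% of its peaks. It was first run with 100 simulations, of which it called 11 without a difference, and was extended to 400 because that number was high.

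The main tests, a first set of alternatives and the rule for the peaks named in the text were fixed before the data were examined. The rule took the 10 overlapping RARβ peaks with the highest fold enrichment, the 10 with the highest score, the 10 non-overlapping peaks with the highest fold enrichment and the 10 widest H3K4me3 peaks. Tests of summit position, of peak density by width, of the distance of non-overlapping peaks of 5 Mb windows, of groups of peaks and of relations across pairs were added after the data had been seen, as were some of the alternatives. The files pair no peak with a gene, and an annotation or sequence of build mm9 was not used here. For that reason the comparisons planned for transcription start sites, gene lists and sequence motifs were not run, peaks are named by position, and which genes or gene parts they lie in is not stated.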

Results

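RARβ is a nuclear receptor that binds DNA and regulates transcription in response to retinoic acid. H3K4me3 is a histone modification found at active promoters. Both were mapped in the caudate putamen of wild-type male mice to find where the receptor is bound in this tissue and how its sites relate to the promoter mark. The RARβ list held 8075 peaks with a median width of 646 bp and a median of 10 tags. The H3K4me3 list held 35971 peaks with a median width of 1679 bp and a median of 206 tags. Peaks took up 5.79 Mb in the RARβ list and 81.4 Mb in the H3K4me3 list. Tags in peaks made up 4.55% of the filtered tags of the RARβ library (Wilson 95% interval 4.53 to 4.58) and 48.2% of those of the H3K4me3 library. The median fold enrichment, as the authors' peak caller gave it, was 19.35 for RARβ and 10.27 for H3K4me3. At the depth of the RARβ library, 21.8% of its peaks had only 7 tags, the fewest in the list. Sites with fewer tags were not detectable at this depth. The authors' empirical FDR was above 5% for 17 RARβ peaks, and for 23398 H3K4me3 peaks (65.0%). Of those 17 RARβ peaks, 15 are among the 24 sites picked by the rule for named peaks. That rule ranked overlapping peaks by fold enrichment and by score, and non-overlapping peaks by fold enrichment only. Among these 15 the FDR fell with the score, from 33.33% at 1185.62 to 25% at 1091.59, 20% at 948.94 and 5.88% at 556.8. The median FDR of the RARβ list was 0.09%. At the top of the list few peaks enter the estimate, so a high FDR there need not mean a less reliable site. There was 1 library per antibody.

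The first comparison asked whether RARβ peaks lay where the promoter mark lay. Of the 8075 RARβ peaks, 5244 overlapped an H3K4me3 peak, a share of 64.9% (Wilson 95% interval 63.9 to 66.0). Circular shifts of the RARβ peaks gave 358 overlaps on average, with 95% of the shifts between 315 and 405. The observed number was 14.6 times higher (permutation p = 0.0002, the smallest that 10000 shifts can give). Shifted peaks could land where no read can be placed, so this ratio can be too high. The marked regions covered 4.36% of the effective genome. They held 63.0 RARβ summits per Mb, against 1.65 per Mb in the rest of the effective genome. Seen from the other side, 4704 of the 35971 H3K4me3 peaks held a RARβ peak, a share of 13.1% (Wilson 95% interval 12.7 to 13.4). Among the 12573 H3K4me3 peaks with an FDR of at most 5%, the share was 22.4%. Overlap was found at 73.2% of the 269 RARβ peaks with at least 30 tags and at 52.1% of the 1761 peaks with 7 tags. By fold enrichment there was no steady order, with overlap at 68.3% of the 4038 peaks with the lowest values, 61.2% of the next 3230 and 63.1% of the 807 with the highest. When H3K4me3 peaks were limited to an FDR of at most 5%, the overlapping share was 40.4%, 17.3 times the mean of the shifts.

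Among the overlapping sites, the highest fold enrichment of RARβ was 164.75, at chromosome 5, 25035408 to 25036365, with 62 tags (Poisson 95% interval 47.5 to 79.5) and an FDR of 12.5%. This site lay in an H3K4me3 peak of 2833 bp with a fold enrichment of 52.87. Next were sites on chromosome 1 at 169502458 to 169503770 with 71 tags and on chromosome 2 at 144284225 to 144285436 with 67 tags, both with a fold enrichment of 141.76, at FDRs of 16.67% and 14.29%. Their H3K4me3 peaks differed in strength, with fold enrichments of 7.09 on chromosome 1 and 51.5 on chromosome 2. The site on chromosome 14 at 17407235 to 17408381 had 74 tags, a fold enrichment of 123.27 and an FDR of 20%. It lay in an 11337 bp H3K4me3 peak with 4923 H3K4me3 tags. The 10 overlapping peaks with the highest fold enrichment ranged from 109.47 to 164.75 and from 38 to 74 tags. Of these 10, 6 were also among the 10 with the highest score. The highest score among overlapping peaks was 1091.59, on chromosome 15 at 103330432 to 103332371, with 111 tags, a fold enrichment of 68.97 and an FDR of 25%. Next by score were the sites on chromosomes 14 and 1 given above.

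The 2831 RARβ peaks without H3K4me3 held the site with the highest fold enrichment of the list. It lay on chromosome 1 at 184430747 to 184431566, 9.73 kb from the nearest H3K4me3 peak, with 107 tags (Poisson 95% interval 87.7 to 129), a fold enrichment of 375.3 and an FDR of 0.0%. Second among them was a site on chromosome 2 at 152147189 to 152148243, 2.95 kb from an H3K4me3 peak, with 83 tags, a fold enrichment of 181.85 and an FDR of 33.33%. The third lay on chromosome 4 at 66555073 to 66556489, 27.7 kb away, with a fold enrichment of 127.68 and an FDR of 6.67%. The 10 strongest sites of this kind had fold enrichments from 92.86 to 375.3 and lay 0.998 to 172 kb from an H3K4me3 peak. The farthest of the 10 was on chromosome 2 at 7920587 to 7921649. Across all 2831 peaks the median distance was 14.9 kb, with quartiles of 4.67 and 39.3 kb, and 325 peaks (11.5%) were more than 100 kb away. Within 5 kb of an H3K4me3 peak were 25.9% of them. Shifted peaks that also fell outside were that close in 12.7% of cases, with 95% of the shifts between 11.6% and 13.8% (permutation p = 0.0002). The share of shifted peaks can be too low, since they could land where no read can be placed. With H3K4me3 peaks of an FDR of at most 5%, the share was 8.81%, against 4.98% of shifted peaks.

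Some of the non-overlapping peaks had very many tags and a low fold enrichment. These were chosen after their values were seen. The peak with the most tags, 1577, lay on chromosome 17 at 39979774 to 39985941 and had a fold enrichment of 11.7. A pair on chromosome 2, at 98506225 to 98507809 and at 98502224 to 98503302, had 882 and 573 tags at fold enrichments of 2.17 and 2.28. A peak on chromosome 9 at 35112630 to 35113276 had 405 tags at a fold enrichment of 2.74. Without the 1% of RARβ peaks with the most tags and the 1% widest, the share overlapping H3K4me3 was 64.7%.

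RARβ peaks inside H3K4me3 peaks had more tags but a lower fold enrichment than those outside. The median was 10 tags inside and 9 outside, a difference of 1 tag (permutation p = 0.00766, adjusted p = 0.00958 over 5 measures by the Benjamini-Hochberg method). The median fold enrichment was 19.35 inside and 21.89 outside, a difference of -2.54 (bootstrap 95% interval -3.64 to -1.08, permutation p = 1e-05, the smallest that 100000 permutations can give). Peaks inside were also wider, with a median of 673 bp against 617 bp (permutation p = 1e-05). Their score was higher too, with a median of 77.51 against 71.76, a difference of 5.75 (bootstrap 95% interval 4.095 to 6.8, permutation p = 1e-05). The quartiles overlapped widely, at 15.33 to 26.82 fold inside and 16.63 to 27.08 fold outside. The difference in fold was -1.54 among the 4037 RARβ peaks with the highest scores and -4.49 with H3K4me3 peaks of an FDR of at most 5%. It was 0.0 among the 2475 peaks whose fold enrichment equalled, to within 0.01, a whole number of tags over the genome-wide background. Fold moves in steps of 3.87 among these peaks, so a difference of -2.54 could not show.

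**Figure D1:**
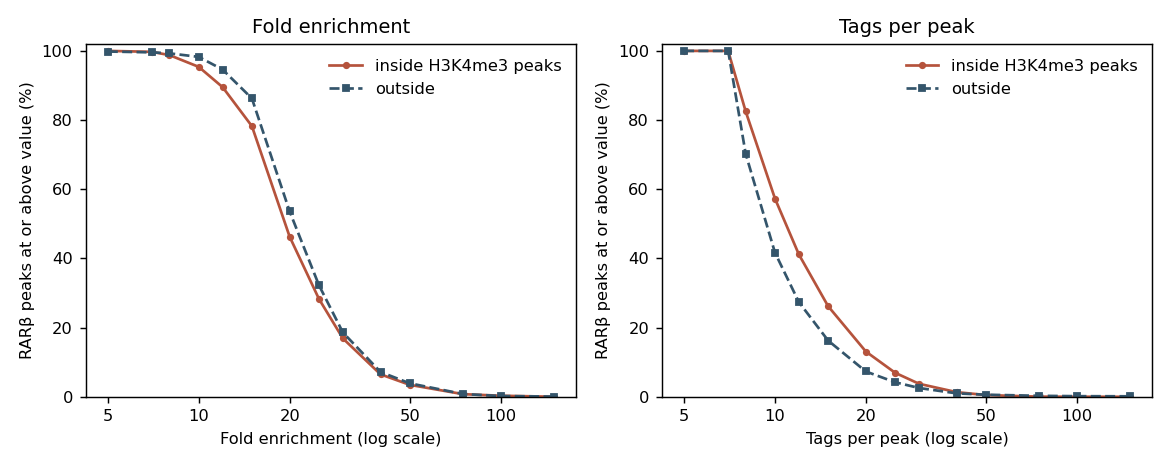
Share of RARβ peaks (percent) with at least the fold enrichment (left) or number of tags (right) on the horizontal log axis, for the 5244 peaks inside H3K4me3 peaks (circles) and the 2831 outside (squares). Inside, 46.3% of peaks reached a fold of 20 and 57.3% reached 10 tags, against 53.6% and 41.7% outside.

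H3K4me3 peaks that held a RARβ peak were wider and stronger than those that held none. Their median width was 2838.5 bp against 1570 bp, a difference of 1268.5 bp (bootstrap 95% interval 1208 to 1347, permutation p = 1e-05). Their median fold enrichment was 19.51 against 9.46, and their median tag number 1059.5 against 179 (permutation p = 1e-05 for each, adjusted p = 1e-05 over 5 measures). A wide peak has more room for an overlap. With the search limited to a fixed 2 kb window around the centre of each H3K4me3 peak, the difference in width was 959 bp. With H3K4me3 peaks of an FDR of at most 5% it was 808 bp. H3K4me3 reads in the RARβ library, or preferential recovery of open chromatin, could also favour H3K4me3 peaks with many tags. Neither was excluded.

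H3K4me3 peaks were divided by width into 10 groups of equal size. RARβ was found at 4.03% of the peaks in the narrowest group, which were 381 to 964 bp wide. In the widest group, with peaks of 4176 bp or more, the share was 35.2% (Wilson 95% interval 33.7 to 36.8). Per length, the narrowest group held 39.7 RARβ summits per Mb (Poisson 95% interval 33.0 to 47.4) and the widest group 75.7 per Mb (72.1 to 79.4), a ratio of 1.91 (exact binomial p = 5.6e-14, two-sided). The 5 groups below the widest one lay between 60.7 and 67.0 per Mb. Summits were spread over the groups unlike length alone would give (chi-square 145, p = 1e-05 by multinomial draws). An FDR of at most 5% was given to 94.0% of the widest group and to 0.0278% of the narrowest.

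**Figure D2:**
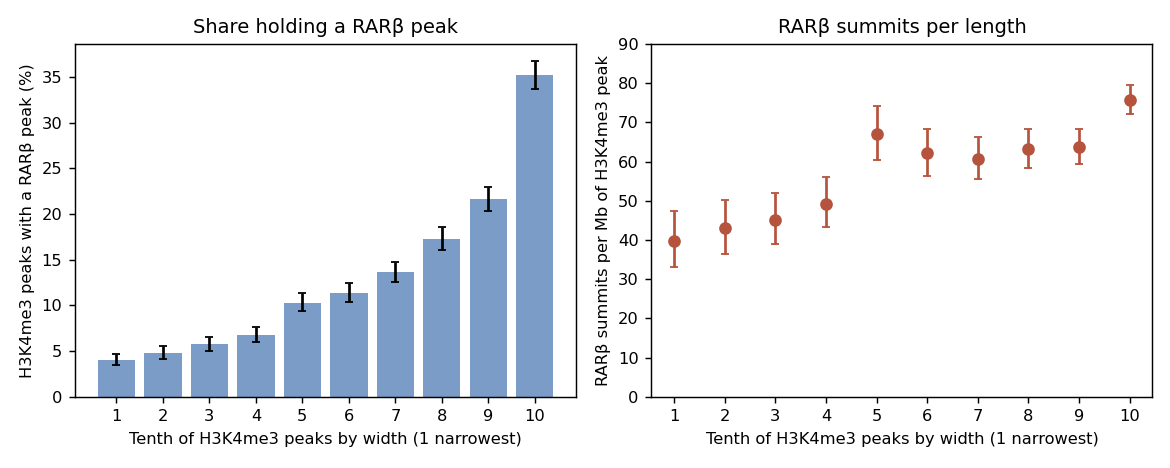
H3K4me3 peaks in 10 groups of equal size by width, from narrowest (1) to widest (10). Bars show the percentage holding a RARβ peak with Wilson 95% intervals, rising from 4.03% to 35.2%, and points show RARβ summits per Mb of H3K4me3 peak with Poisson 95% intervals, from 39.7 to 75.7.

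The 10 widest H3K4me3 peaks were 22.7 to 78.5 kb wide and each held at least 2 RARβ peaks, 41 in all. The widest, on chromosome 17 at 8991315 to 9069783, had 21137 H3K4me3 tags and held 4 RARβ peaks. The strongest of these by tags, with 38, lay at 8993035 to 8995117, near the H3K4me3 summit at 8994913. The second widest, on chromosome 12 at 109207018 to 109245146, was 38.1 kb wide and held 6 RARβ peaks with 9 to 21 tags each. The third, on chromosome 16 at 35152624 to 35188755, was 36.1 kb wide and held 4. The fourth, on chromosome 11 at 119796393 to 119824048, held 4 RARβ peaks, among them one of 64 tags at 119798345 to 119800997. The fifth, on chromosome 2 at 115876633 to 115902684, held 5, the strongest with 45 tags and a fold enrichment of 58.6 at 115896409 to 115897675. Others among the 10 were on chromosome 12 at 50473540 to 50498243 with 3 RARβ peaks, and on chromosome 13 at 83857826 to 83882185 with 5. The ninth, on chromosome 15 at 103331496 to 103355012, held 4, and its lower edge carried the overlapping RARβ peak with the highest score. The summit of that RARβ peak, at 103331226, lay outside the H3K4me3 peak.

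**Figure D3:**
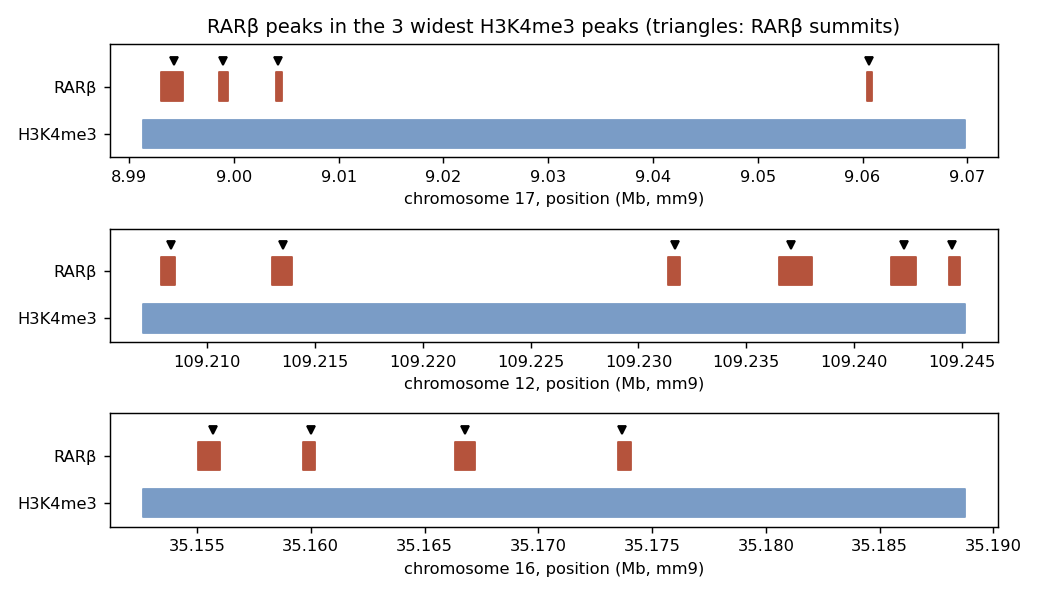
Maps of the 3 widest H3K4me3 peaks (lower bars) with the RARβ peaks inside them (upper bars, triangles at summits), drawn to scale against mm9 position in Mb. They held 4, 6 and 4 RARβ peaks on chromosomes 17, 12 and 16.

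Within the mark, RARβ summits lay close to the H3K4me3 summit. Of the RARβ peaks, 5131 had their summit inside an H3K4me3 peak. Their median distance from its summit was 345 bp, with quartiles of 139.5 and 713 bp. Placing each summit at random within its H3K4me3 peak gave a median of 691 bp, with 95% of draws between 669 and 712 bp (permutation p = 0.0002). With each H3K4me3 peak divided into 10 equal parts, the middle 4 parts held 61.1% of the RARβ summits and the 2 outer parts 4.39%. Across the 5244 overlapping pairs, the number of RARβ tags was weakly related to the number of H3K4me3 tags, with Spearman's rho of 0.12 and Pearson's r of 0.124, and about as weakly to H3K4me3 width, with rho of 0.108 and r of 0.11. It had no relation past the threshold by rank to H3K4me3 fold enrichment (rho -0.0154, permutation p = 0.264; r -0.0293, permutation p = 0.0326). RARβ fold enrichment fell with H3K4me3 tags, with rho of -0.29 and r of -0.16 (permutation p = 0.0001 for each coefficient with tags or width, the smallest that 10000 permutations can give, adjusted p of at most 0.00015 over 6 relations). These relations are across peaks of single libraries, and peaks are not independent replicates.

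**Figure D4:**
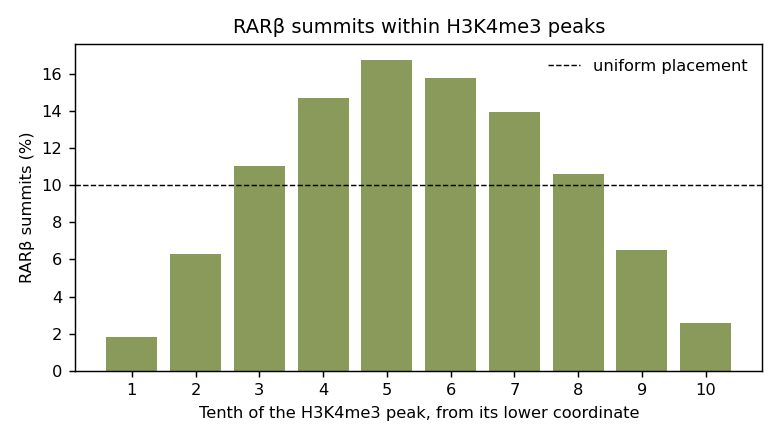
Percentage of the 5131 RARβ summits in each of 10 equal parts of the H3K4me3 peak that holds them, counted from its lower coordinate. The dashed line marks uniform placement at 10% per part, and part 5 holds 16.8% against 1.83% and 2.55% in the outer ones.

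RARβ peaks also occurred in groups. Of all peaks, 2277 (28.2%) had a neighbour with a summit within 10 kb, forming 955 groups of 2 or more, of which 75 had 4 or more. No chance value was computed for these numbers. The 4 largest groups, chosen after their values were seen, had 8 peaks each. They lay on chromosome 14 at 71017699 to 71031853 with 7 peaks in H3K4me3 peaks, and on chromosome 11 at 77654087 to 77689675 with 5. The others lay on chromosome 4 at 137203976 to 137238004 and on chromosome 3 at 17685564 to 17705782, each with all 8 in H3K4me3 peaks. A group of 7 on chromosome 11 at 98206406 to 98217969 lay in a single H3K4me3 peak of 16856 bp.

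RARβ peaks were unevenly spread over the chromosomes relative to H3K4me3 peaks (chi-square 154 over autosomes and X, p = 1e-05 by multinomial draws). The X chromosome, present in 1 copy in male mice, had 52 RARβ peaks. The autosomal ratio of RARβ to H3K4me3 peaks gave an expectation of 175 for X, so the observed number was 0.296 of it (Poisson 95% interval 0.221 to 0.389). Chromosome 12 had 455 peaks, 1.33 times the expectation (1.21 to 1.46), the highest ratio of the autosomes, and chromosome 3 had the lowest at 0.874 (0.789 to 0.966). The unevenness remained over autosomes alone (chi-square 66.8, p = 1e-05 by multinomial draws). The draws, and the simulated checks, took peaks as independent and the H3K4me3 numbers as exact, so these p-values can be too small. The share of RARβ peaks inside H3K4me3 peaks was 67.3% on X (Wilson 95% interval 53.8 to 78.5) and 64.9% on autosomes. All 3 RARβ peaks on Y overlapped an H3K4me3 peak.

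In autosomal 5 Mb windows with at least 20 H3K4me3 peaks, 21 of 444 windows had more RARβ peaks than the autosomal ratio gave and 2 had fewer (exact binomial test, two-sided, adjusted over the windows). The test took the expected number as exact and peaks as independent, although 28.2% of the RARβ peaks lay in groups. Its p-values can therefore be too small. Where few peaks were expected, a shortage could hardly pass the threshold, so the 21 and the 2 are not a fair contrast. The lowest p was at 95 to 100 Mb of chromosome 6, where 49 RARβ peaks were found against 18.7 expected, a ratio of 2.62 (exact binomial, adjusted p = 1.69e-06). Of these 49, 18 lay in H3K4me3 peaks. On chromosome 8, the window from 75 to 80 Mb had 26 peaks against 7.06, a ratio of 3.68 (exact binomial, adjusted p = 7.39e-06). On chromosome 12, the window from 105 to 110 Mb, which holds the second widest H3K4me3 peak, had 64 peaks against 30.1, a ratio of 2.13 (exact binomial, adjusted p = 1e-05).

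**Figure D5:**
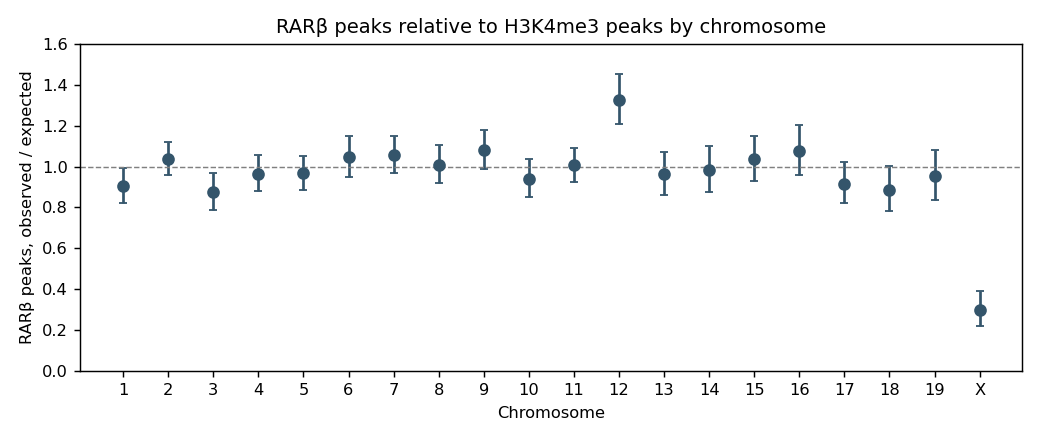
RARβ peaks on each chromosome divided by the number expected from its H3K4me3 peaks at the autosomal ratio, with Poisson 95% intervals; the dashed line marks a ratio of 1. X lies at 0.296 and chromosome 12 at 1.33.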

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

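Of 56 alternatives, 32 were planned and 24 were chosen after seeing the data, the latter being all those on summit distance, density by width and distance outside, those with H3K4me3 peaks of an FDR of at most 5%, and others named below. Of those with a test, 42 kept the direction and the side of the threshold of their result, and 6 medians without a test stayed within the 95% interval of the main value. The overlapping share of RARβ peaks ranged from 40.4% to 68.2% over 11 alternatives, each above its shifts. The difference in width of H3K4me3 peaks ranged from 808 to 1320 bp over 7 alternatives. The chi-square statistic over chromosomes ranged from 66.8 to 290 over 4. Among peaks with the local background at the genome-wide floor, the difference in median fold between RARβ peaks inside and outside H3K4me3 peaks was 0.0. Fold moves there in steps of 3.87, so a smaller difference could not show. The difference turned to 1.0 tag higher inside when tags were compared in place of fold. The other 5 alternatives for this difference gave -4.49 to -1.54. The tag and floor alternatives were chosen after seeing the data, as were the chromosome alternatives with autosomes only and with the H3K4me3 peaks of highest score, and the fold and width alternatives without extreme peaks. By construction, keeping the 50% of peaks with the highest scores raised the median fold to 26.8 for RARβ and 22.3 for H3K4me3. Alternatives for transcription start sites, gene lists, motifs and chromosome length were not run, since a genome of build mm9 was not used here. No paired analysis was possible because there was 1 library per antibody, and no replicate could be left out.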

Other observations

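The tests of the 5 Mb windows, of reads from the H3K4me3 library, of X and of the mean fold at the background floor were chosen after the result was seen. Further 5 Mb windows with more RARβ peaks than the autosomal ratio to H3K4me3 peaks gave were found on chromosome 2 from 5 to 10 Mb, with 33 peaks against 11.6 expected, and on chromosome 16 from 5 to 10 Mb, with 36 against 14.4. The neighbouring window of chromosome 16, from 10 to 15 Mb, had 38 against 16.2. In these windows 14, 19 and 23 of the RARβ peaks lay in H3K4me3 peaks.

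RARβ peaks were scarce on X, with 52 found against 175 expected from its H3K4me3 peaks (95% Poisson range 150 to 202), so a lower number of marked regions on X does not account for it. A single copy of X in males may lower its tags, so that peaks near the calling floor are missed, but no test isolated copy number. If a peak on X needed the score of an autosomal peak of at least 100, 2 times the floor of 50, 48.2 peaks would remain (95% range 35 to 62), which includes the 52 found. At stricter score limits of 60, 75, 100 and 150, X had 42, 19, 9 and 5 peaks, against 32.6, 20.3, 10.1 and 3.26 under the same rule, each within its 95% range. The most highly tagged H3K4me3 peaks were also lower on X, with the 99th percentile of tags at 0.635 of that on autosomes, while the median was 2.74 times the autosomal one, and a true scarcity of RARβ sites on X stays open as untested.

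Reads of the deep H3K4me3 library in the shallow RARβ library are a candidate explanation for the high overlap of RARβ with H3K4me3 peaks. The prediction was that such reads would put a RARβ peak on most of the densest H3K4me3 peaks. Of the 10% of peaks with the most tags per kb, 69.5% held none (95% interval 68.0 to 71.0). With few such reads, many dense peaks could stay below the 7 tags of the smallest RARβ peaks, so this share cannot decide the question. The share holding a RARβ peak rose from 6.45% to 30.5% between the 10% of H3K4me3 peaks with the fewest and the most tags per kb. Such reads stay open as a source of part of the overlap, though not of every overlapping site. On chromosome 1 at 169502458 to 169503770, 71 RARβ tags lay at an H3K4me3 peak of only 97 tags. The RARβ library had 2237580 filtered tags against 47461843, so such reads would give far fewer tags there. How many sites are of this kind was not counted. If low coverage of the shared control let both lists call the same places, RARβ peaks with a local background at the genome-wide floor would overlap more often, but they did so in 55.9% of 2475 peaks against 68.9% of the other 5600, a difference of -13.0 percentage points (Fisher's exact test, two-sided, p = 4.82e-29). By the bound set before this result was seen, that counted against low control coverage. A raised local background demands more tags for a call, however, and overlap rose with tags, from 52.1% at 7 tags to 73.2% at 30 or more. The gap can come from that, so the comparison cannot decide the question. Preferential recovery of open chromatin was not tested, and no biological explanation was either. H3K4me3 reads or such recovery could also bear on the results for H3K4me3 peak width, RARβ density and summit distance. Neither was tested for those results.

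Inside H3K4me3 peaks RARβ peaks had more tags but a lower fold enrichment. Removing the 1% of peaks with the most tags and the 1% widest left the difference in median fold at -2.32 (permutation p = 1e-05). A median hardly responds to the removal of so few peaks, so this outcome was largely set by the measure. A higher local background in the control inside H3K4me3 peaks is a candidate explanation that these data leave open. The local background was at the genome-wide floor for 26.4% of peaks inside and 38.5% of those outside. Among peaks above the floor the median fold was lower inside, at 17.88 against 19.16. The local background varies among these peaks, so this contrast does not set it aside. Among peaks at that floor the mean fold was 27.8 inside and 27.1 outside, a difference of 0.682 (permutation p = 0.26), with the mean used after the medians were seen to be tied (difference 0.0, permutation p = 1). At the floor the fold is a fixed multiple of the summit's tags and moves in steps of 3.87, so a median difference of -2.54 could not show. The mean showed no difference past the threshold. The higher tag number inside was counted over whole peaks, which were also wider there, so it is another measure. The comparison decides nothing. No biological explanation was tested.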
